A study of Homo sapiens with 12 samples.

How the data were processed

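RNA was measured by polyA-selected RNA sequencing in 12 libraries of LM3 cells, a lung-metastatic derivative of the human triple-negative breast cancer line MDA-MB-231. The libraries form 4 groups of 3: a control short hairpin RNA (shControl), a hairpin against ACSL5 (shACSL5), and the same pair of cell types treated with palmitic acid (shControl_PA and shACSL5_PA). Groups and replicate numbers were taken from the sample labels. The dose, duration and vehicle of palmitic acid and the hairpin sequence are not given in the sources used here. An effect of a vehicle therefore cannot be told apart from that of palmitic acid. Nothing in the labels says that the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

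The authors deposited raw read counts per gene, whole numbers that were not normalized. Per the submitters' processing notes, fastp 0.22.0, HISAT2 2.1.0 and featureCounts (version not given) were used with the GRCh38 build. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The table held 57730 genes, of which 51928 Ensembl identifiers matched a current symbol, and current symbols replaced the table's own for 21216 genes. The mitochondrially encoded genes were at 0 in every library and could not be analysed. Library totals ran from 16788694 to 21814751 counts.

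Genes were kept with edgeR's filterByExpr, which left 14706. Counts were scaled with TMM factors, and 1 negative binomial model was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, Benjamini-Hochberg adjustment). Counting intervals are exact binomial ones of summed counts and cover counting error only. The common dispersion was 0.00203. A gene was called at an adjusted p under 0.05. Every adjusted p for a gene comes from this test, unless an alternative is named with it. The contrasts tested were the knockdown without and with palmitate, palmitate in control and in knockdown cells, and the interaction, which is the palmitate response in knockdown cells minus that in control cells. Changes are log2 ratios with a standard error (SE) derived from the test, the absolute coefficient divided by the square root of its F statistic. This SE is approximate and can be too small for large changes that rest on few counts. Levels are means of TMM-scaled CPM (counts scaled to library size) ± SD over 3 libraries.

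Before the data were examined, the tests, the alternatives, 30 gene lists and the rule for naming genes were fixed. The named genes were the ACSL family and, per comparison, the 6 largest rises and 6 largest falls among called genes with a mean CPM of at least 5 and no overlap between the libraries of the groups (this last filter was dropped for the interaction). Up to 4 called members with the smallest p were added from each list with at least 2 called members. A fixed set (PDK4, ANGPTL4, CPT1A, PLIN2, DDIT3, ATF3, TRIB3, SCD, IL6 and CXCL8) was added in the palmitate comparisons and the interaction. Some further values of these genes in other comparisons are given for reading the differences and were chosen after they were seen. Some members of these lists are counted in the totals but are not reported here by gene.

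The 26 lists with at least 5 measured members were tested with camera from limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists. Each was tested again with a correlation estimated from the data and with fry. The lists cover acyl-CoA synthetases and fatty acid uptake, PPAR targets, mitochondrial beta-oxidation, SREBP2 cholesterol biosynthesis, SREBP1 fatty acid synthesis, triglyceride synthesis and lipid droplets, sphingolipid and ceramide synthesis, the ATF4 integrated stress response, endoplasmic reticulum (ER) chaperones, NRF2 antioxidant targets, ferroptosis, NF-kB and inflammatory cytokines, interferon-stimulated genes, MHC class I antigen presentation, mesenchymal and matrix genes, epithelial genes, the lung metastasis signature of MDA-MB-231, S phase, G2/M, hypoxia and glycolysis, nuclear subunits of oxidative phosphorylation (OXPHOS), mitochondrially encoded genes, YAP targets, immediate early genes, heat shock, autophagy and lysosome, and markers of immune, endothelial, lung epithelial and luminal breast cells. ACSL5 is in none of them. For every list called with the preset correlation, the median, the mean and the test had the same sign. Among uncalled lists the signs of these differed for beta-oxidation, sphingolipid, ER and autophagy genes with the knockdown, and for SREBP2, triglyceride and immediate early genes with palmitate in control cells. They also differed for epithelial, immediate early and luminal genes with palmitate in knockdown cells, for PPAR, SREBP1 and autophagy genes with the knockdown under palmitate, and for the lung metastasis, hypoxia and autophagy lists in the interaction.

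The fits were tested on simulated counts with the real means and library sizes, in which 200 genes were changed by known folds. For the knockdown without palmitate, run on 14469 simulated genes, 60% of the smallest simulated changes (smaller than 1.5-fold), 70% of 1.5-fold, 86% of 2-fold and 100% of 4-fold changes were recovered, and 8.20% of calls were false. For the interaction on the same number of genes, 24% of the smallest, 50% of 1.5-fold and 74% of 2-fold changes were recovered, and 5.26% of calls were false. Far fewer genes were changed than were called in the real data, so the adjusted threshold differed and these shares need not hold there.

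Replicates were compared by a chi-square of their counts, which gave 2.24 to 4.36 per degree of freedom over the 12 pairs, so no pair differed by as little as sampling noise and all were counted. Of 253 named genes checked against GENCODE 29 on GRCh38 (4 of them looked up by symbol), 24 have uncertain counts, because over 25% of the exon length overlaps another gene or over 20% of the 50-base sequences occur elsewhere. Those named below are ASNS, CST1, DDIT3 (overlapping MARS1), DNAJC25-GNG10, FTH1, HSPD1, KRT18, KRT8, RN7SL1, RN7SL2 and SYNC. Coordinates and 3′ UTR sequences come from the same annotation, which may not be the release used for the counting.

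Alternatives were relative log expression (RLE) size factors, library sizes alone, no low-count filter, a minimum of 5 CPM in 3 libraries, a replicate block, leaving out each library, DESeq2 1.42.0, fitting only the compared groups, and a 2-fold threshold. Leaving out genes with a heptamer found in the analysis, and library sizes alone for the ratio of spreads, were added after seeing the data. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and bedtools 2.31.1.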

Results

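The transcriptome of LM3 breast cancer cells was compared between control and ACSL5-deficient cells, each with and without palmitic acid, a saturated long-chain fatty acid. ACSL5 is a long-chain acyl-CoA synthetase, an enzyme that activates fatty acids for further metabolism, and the series asks about its part in the spread of breast tumours to the lung. There were 3 libraries in each of 4 groups, with 17119570 to 18680316 counts in shControl, 16788694 to 21814751 in shACSL5, 18014888 to 18614091 in shControl_PA and 18875565 to 20623983 in shACSL5_PA. The first principal component held 47.4% of the variance and separated knockdown from control libraries, and the second held 12.8% and separated treated from untreated libraries.

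ACSL5 (ENSG00000197142, GRCh38 chromosome 10, 112374018 to 112428380, plus strand) stood at 143 ± 1.69 CPM in shControl and 11.2 ± 1.16 CPM in shACSL5, so that 7.82% of the transcript remained (SD, n = 3). With palmitate the levels were 191 ± 2.73 CPM in shControl_PA and 15.3 ± 2.19 CPM in shACSL5_PA, leaving 8.01%. All 3 knockdown libraries lay below all 3 controls in each pair, and the 2-sided exact permutation test gave p = 0.1, the smallest it can give with 3 against 3. The model gave log2 changes of -3.67 (SE 0.07, adjusted p = 4.2e-21) and -3.65 (SE 0.06, adjusted p = 3.49e-21). Palmitate raised ACSL5 itself by 0.41 (SE 0.05) in control and 0.44 (SE 0.09) in knockdown cells on the log2 scale, and the interaction was 0.03 (SE 0.10, adjusted p = 0.897). Among its relatives, ACSL3 fell by 0.55 and ACSL4 by 0.29 on the log2 scale with the knockdown, while ACSL1 stood at 0.14 (SE 0.06, adjusted p = 0.0509, and 0.0200 to 0.184 over the alternatives).

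**Figure D1:**
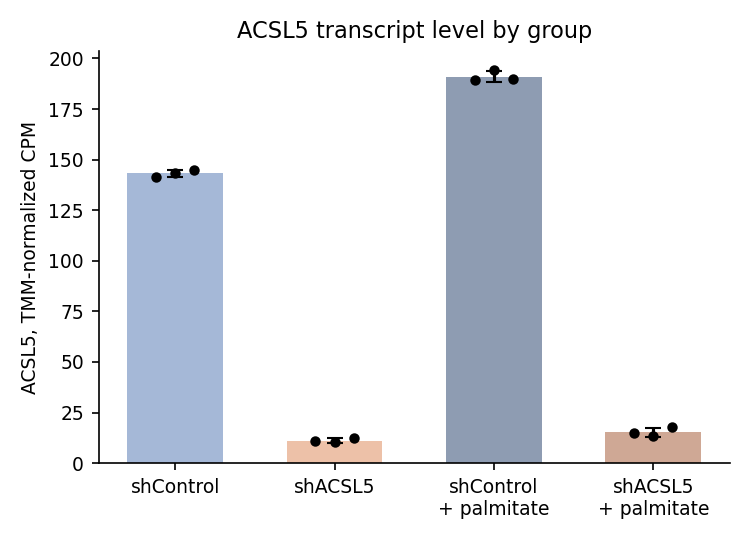
ACSL5 level (CPM) in each of the 12 libraries, with points for libraries and the mean ± SD of each group. The knockdown groups average 11.2 and 15.3 CPM against 143 and 191 CPM in their controls.

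The knockdown without palmitate, which asks what loss of ACSL5 changes in untreated cells, moved some genes by large factors. STXBP6, which encodes a syntaxin-binding protein, rose from 0.112 ± 0.101 to 14.4 ± 1.46 CPM (log2 6.96, SE 0.29), a fold that rests on 6 counts over the shControl libraries (95% counting interval 5.92 to 8.50). The secreted proteoglycan gene ESM1 rose by 4.78 (SE 0.24), the phosphodiesterase PDE1C by 2.93 (SE 0.18), the vasoactive peptide gene ADM by 2.85 (SE 0.13) and SUSD2 by 2.78 (SE 0.10). DPYSL3, a regulator of the cytoskeleton, fell from 30.6 ± 1.67 to 2.57 ± 0.228 CPM (log2 -3.57, SE 0.13). AFAP1L2 (-3.01, SE 0.19), SYNC (-2.97, SE 0.23, 48.9% of its exons overlapping RBBP4), JCAD (-2.76, SE 0.12) and SHISAL1 (-2.74, SE 0.24) fell too. SPHK1, which makes sphingosine 1-phosphate, rose by 2.43 (SE 0.11), and FTL, the ferritin light chain, by 1.32 (SE 0.03) to 1268 ± 23.3 CPM.

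In all, 9164 of 14706 genes were called, 4363 higher and 4801 lower (47.6% higher, 44.7% to 50.5% over the alternatives), and 1485 of them changed at least 2-fold. Genes of cholesterol synthesis fell: 15 of 23 measured SREBP2 targets fell and 3 rose, with the same counts adjusted over the list alone. The list test gave adjusted p = 0.0144 (adjusted p = 0.0816 with an estimated correlation). HMGCS1 fell by 0.75 (SE 0.04), FDFT1 by 0.69 (SE 0.03) and MSMO1 by 0.86 (SE 0.04). Both mesenchymal and epithelial genes fell. Of 23 mesenchymal and matrix genes 15 fell and 3 rose, also when adjusted over the list alone (adjusted p = 0.000617, adjusted p = 0.0816 with an estimated correlation). They include the matrix glycoprotein TNC (-1.44, SE 0.04), COL6A2 (-1.26, SE 0.04), TGFBI (-1.44, SE 0.06) and VIM (-0.59, SE 0.02). Of 13 epithelial genes 8 fell and 3 rose, also when adjusted over the list alone (adjusted p = 0.0358, adjusted p = 0.143 with an estimated correlation). CLDN4 stood at -1.69 (SE 0.08), DSP at -1.56 (SE 0.07), OCLN at -1.54 (SE 0.12) and KRT19 at -1.02 (SE 0.07). The luminal breast list, made of markers of another kind of breast cell, which shares KRT8, KRT18 and KRT19 with it, had 6 of 9 members lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.0358, adjusted p = 0.391 with an estimated correlation). It was led by AGR2 (-1.91, SE 0.13).

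Replication genes rose with the knockdown: 22 of 27 S phase genes rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 2.01e-06, adjusted p = 0.0816 with an estimated correlation). The helicase subunits MCM2 and MCM4 rose by 0.88 (SE 0.04) and 0.69 (SE 0.03), CDC25A by 0.86 (SE 0.05) and E2F1 by 0.73 (SE 0.04). Summed histone transcripts, which are largely not polyadenylated and depend on the selection of RNA, were at 56.6 ± 1.87 CPM in shControl and 105 ± 1.09 CPM in shACSL5. Of 36 nuclear OXPHOS subunits 20 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.0144, adjusted p = 0.450 with an estimated correlation). COX5A was among the 3 that fell, from 98.0 ± 3.41 to 32.0 ± 2.23 CPM (log2 -1.62, SE 0.06). Heat shock genes rose in 11 of 16 members and fell in 3 (12 and 3 adjusted over the list alone, adjusted p = 0.000617, adjusted p = 0.0717 with an estimated correlation). The members that rose include the cochaperone FKBP4 (0.66, SE 0.03) and HSPA8 (0.36, SE 0.02). YAP targets rose in 12 of 23 members and fell in 5 (12 and 6 adjusted over the list alone, adjusted p = 0.0358, adjusted p = 0.152 with an estimated correlation). ANKRD1 rose by 2.74 (SE 0.05), FJX1 by 1.21 (SE 0.06) and F3 by 1.02 (SE 0.04), while CCN2 fell by 0.69 (SE 0.03).

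Of 35 integrated stress response genes 18 fell and 12 rose (19 and 12 adjusted over the list alone, adjusted p = 0.350). Those that fell include CHAC1 (-2.27, SE 0.14), DDIT4 (-1.36, SE 0.06) and the amino acid enzyme ASNS (-1.10, SE 0.04). Of 27 interferon-stimulated genes 16 fell and 4 rose (17 and 4 adjusted over the list alone, adjusted p = 0.0819). DDX60 stood at -2.19 (SE 0.12) and SAMD9L at -1.36 (SE 0.09). Of the falling genes named for the knockdown, ACSL3, JCAD, FDFT1, CHAC1 and DDX60 carry in their 3′ UTR the heptamer ACTACTT, which also occurs in coding exon 16 of ACSL5 (GRCh38 chromosome 10, 112422007 to 112422013, in the context TGACATGAACTACTTTACAGTG). STXBP6, which rose, carries it too. Endothelial markers were few and mostly low: CDH5 fell from 1.16 ± 0.476 to 0.103 ± 0.141 CPM, ESAM fell by 0.43 (SE 0.06) from 55.0 ± 1.60 CPM, and KDR was called at -0.97 (SE 0.31) but not without shControl replicate 1 (-0.63, adjusted p = 0.119). RIOX1 was called at 3.96 (SE 0.82), but it rests on libraries that scattered widely, at 0.677 ± 1.17 CPM in shControl and 10.8 ± 7.74 CPM in shACSL5. Without shControl replicate 2, the remaining control libraries of RIOX1 held 0 counts and the fitted value of 10.6 was no bound.

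Palmitate in control cells, the response to the fatty acid with ACSL5 present, raised inflammatory genes and PPAR targets. The chemokine CXCL8 rose from 1.69 ± 0.428 to 29.2 ± 1.12 CPM (log2 4.10, SE 0.14) and the prostaglandin synthase PTGS2 from 6.72 ± 0.266 to 53.5 ± 2.45 CPM (log2 2.99, SE 0.09). ANGPTL4, a lipase inhibitor and PPAR target, rose by 3.00 (SE 0.15), PDK4, which restrains glucose oxidation, by 1.77 (SE 0.10), the stress cytokine GDF15 by 1.61 (SE 0.16) and the phosphatase DUSP1 by 1.55 (SE 0.05). AFAP1L2 fell by 2.56 (SE 0.19), the transglutaminase F13A1 by 1.61 (SE 0.16), SHISAL1 by 1.58 (SE 0.22), CST1 by 1.56 (SE 0.27, sequence shared with its family), ZNF250 by 1.41 (SE 0.10) and CRIP2 by 1.34 (SE 0.17).

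There were 4217 genes called, 2227 higher and 1990 lower (52.8% higher, from 35.9% with library sizes alone to 57.8% with DESeq2), and 240 changed at least 2-fold. PPAR targets rose in 9 of 14 members and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 2.65e-08). CPT1A, the gate of mitochondrial fatty acid import, rose by 1.29 (SE 0.05) and the lipid droplet coat gene PLIN2 by 1.03 (SE 0.05). Of 18 beta-oxidation genes 7 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00188, adjusted p = 0.0593 with an estimated correlation), ACADVL by 0.76 (SE 0.03). NF-kB targets and cytokines rose in 14 of 23 members and fell in 1, also adjusted over the list alone (adjusted p = 1.65e-07). NFKBIZ stood at 1.21 (SE 0.12) and the inhibitor NFKBIA at 1.02 (SE 0.06). IL6 stood at -0.86 (SE 0.45, adjusted p = 0.163) and was near the floor, at 1.01 ± 0.242 CPM without palmitate.

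Of 35 integrated stress response genes 24 rose and 0 fell (25 and 0 adjusted over the list alone, adjusted p = 9.5e-14). They include SESN2 (0.95, SE 0.08), PPP1R15A (0.92, SE 0.04), ATF3 (0.93, SE 0.12), TRIB3 (0.64, SE 0.09) and DDIT3 (1.07, SE 0.14, its exons overlapping MARS1). Of 24 ER chaperone genes 19 rose and 0 fell, also adjusted over the list alone (adjusted p = 2.4e-14). HSPA5 stood at 0.60 (SE 0.02) and HERPUD1 at 0.63 (SE 0.05). NRF2 targets rose in 13 of 22 members and fell in 1 (13 and 2 adjusted over the list alone, adjusted p = 1.3e-08). FTL stood at 0.87 (SE 0.03) and TXNRD1 at 0.57 (SE 0.03). Hypoxia and glycolysis genes rose in 21 of 27 members and fell in 0 (23 and 0 adjusted over the list alone, adjusted p = 7.63e-19). P4HA1 stood at 0.71 (SE 0.04) and NDRG1 at 0.55 (SE 0.04). Heat shock genes rose in 12 of 16 and fell in 0, also adjusted over the list alone (adjusted p = 8.87e-10). Ferroptosis genes rose in 9 of 20 and fell in 3, also adjusted over the list alone (adjusted p = 0.000711). Autophagy and lysosome genes rose in 10 of 25 and fell in 3 (10 and 5 adjusted over the list alone, adjusted p = 0.0191, adjusted p = 0.200 with an estimated correlation). The autophagy adaptor SQSTM1 rose by 1.04 (SE 0.03).

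Of 27 S phase genes 13 rose and 0 fell (15 and 0 adjusted over the list alone, adjusted p = 1.09e-05). Of 30 G2/M genes 11 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 0.0011). MCM2 stood at 0.26 (SE 0.04) and AURKB at 0.25 (SE 0.05). Histone transcripts were at 50.6 ± 3.38 CPM in shControl_PA. OXPHOS subunits rose in 10 of 36 members and fell in 0 (11 and 0 adjusted over the list alone, adjusted p = 0.00921, adjusted p = 0.233 with an estimated correlation). Mesenchymal and matrix genes fell in 17 of 23 members and rose in 3, also adjusted over the list alone (adjusted p = 1.3e-08). COL5A1 stood at -0.81 (SE 0.07) and S100A4 at -1.21 (SE 0.14). YAP targets fell in 8 of 23 and rose in 2, also adjusted over the list alone (adjusted p = 0.00392). Epithelial genes fell in 4 of 13 and rose in 1, also adjusted over the list alone (adjusted p = 0.0203, adjusted p = 0.0591 with an estimated correlation). SCD was at -0.07 (SE 0.02, adjusted p = 0.0136), a call lost without shControl replicate 2 (adjusted p = 0.0579), shControl replicate 3 (0.0615) or shControl_PA replicate 2 (0.0745) and with no low-count filter (0.0893).

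Palmitate in knockdown cells, the response with ACSL5 reduced, again raised PPAR targets and, by less than in control cells, CXCL8 and PTGS2. ANGPTL4 rose from 2.09 ± 0.467 to 17.6 ± 1.30 CPM (log2 3.07, SE 0.15) and PDK4 from 2.34 ± 0.415 to 17.4 ± 0.745 CPM (log2 2.90, SE 0.12). CXCL8 rose by 1.88 (SE 0.14) and PTGS2 by 1.70 (SE 0.10). ESM1, which the knockdown had raised, fell by 1.71 (SE 0.17) and PDE1C by 1.33 (SE 0.15), along with FILIP1L (-1.52, SE 0.14), the transcription factor FOXQ1 (-1.23, SE 0.09), the cytokine signalling inhibitor SOCS3 (-1.20, SE 0.05) and FHL1 (-1.19, SE 0.19). RN7SL1 and RN7SL2, RNA components of the signal recognition particle with 100% and 86.45% of their 50-base sequences found elsewhere, were called at 1.90 (SE 0.37) and 2.37 (SE 0.46), and the counting could have split their reads.

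There were 3216 genes called, 1778 higher and 1438 lower (55.3% higher, from 46.1% with library sizes alone to 59.6% with no low-count filter), and 136 changed at least 2-fold. PPAR targets rose in 10 of 14 members and fell in 0, also adjusted over the list alone (adjusted p = 7.77e-13). CPT1A stood at 1.42 (SE 0.05), VLDLR at 0.74 (SE 0.08) and PLIN2 at 0.77 (SE 0.05). Beta-oxidation genes rose in 8 of 18 and fell in 0, also adjusted over the list alone (adjusted p = 3.24e-06). ACADVL stood at 0.80 (SE 0.03). Cholesterol synthesis genes rose in 9 of 23 and fell in 0 (12 and 0 adjusted over the list alone, adjusted p = 7.25e-05). IDI1 stood at 0.30 (SE 0.04), HMGCS1 at 0.26 (SE 0.04) and STARD4 at 0.29 (SE 0.05). SCD, the stearoyl-CoA desaturase, rose by 0.25 (SE 0.02). NF-kB targets rose in 11 of 23 and fell in 2 (12 and 2 adjusted over the list alone, adjusted p = 1.49e-05). NFKB2 stood at 0.50 (SE 0.04), and IL6 stood at 0.02 (SE 0.48, adjusted p = 0.979). TNFAIP3 stood at -0.10 (SE 0.15, adjusted p = 0.673) after a rise of 1.42 (SE 0.15) in control cells.

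Of 35 integrated stress response genes 17 rose and 2 fell (21 and 2 adjusted over the list alone, adjusted p = 7.77e-08). DDIT4 stood at 0.98 (SE 0.06) and SESN2 at 0.85 (SE 0.08), while DDIT3 stood at 0.29 (SE 0.13, adjusted p = 0.125) and ATF3 at 0.27 (SE 0.11, adjusted p = 0.0727, and 0.0490 without shACSL5_PA replicate 2 to 0.252 without shACSL5_PA replicate 1). ER chaperones rose in 14 of 24 and fell in 0, also adjusted over the list alone (adjusted p = 8.54e-08). Hypoxia genes rose in 20 of 27 and fell in 0 (22 and 1 adjusted over the list alone, adjusted p = 9.03e-17). Heat shock genes rose in 7 of 16 and fell in 0 (9 and 0 adjusted over the list alone, adjusted p = 0.000575). VEGFA rose by 0.66 (SE 0.05) and ENO2 by 0.74 (SE 0.05). Ferroptosis genes rose in 10 of 20 and fell in 2 (12 and 2 adjusted over the list alone, adjusted p = 9.34e-05). MHC class I genes rose in 7 of 16 and fell in 0 (7 and 1 adjusted over the list alone, adjusted p = 0.0043). TAP1 stood at 0.38 (SE 0.07). YAP targets fell in 9 of 23 and rose in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.000575), ANKRD1 by 0.42 (SE 0.04). NRF2 targets rose in 9 of 22 and fell in 0, also adjusted over the list alone (adjusted p = 0.00308, adjusted p = 0.0511 with an estimated correlation). Interferon-stimulated genes fell in 9 of 27 and rose in 1 (10 and 2 adjusted over the list alone, adjusted p = 0.0031, adjusted p = 0.0950 with an estimated correlation). IFIT2 stood at -0.53 (SE 0.06). Autophagy genes rose in 8 of 25 and fell in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.00149, adjusted p = 0.0986 with an estimated correlation). MAP1LC3B stood at 0.42 (SE 0.03).

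**Figure D2:**
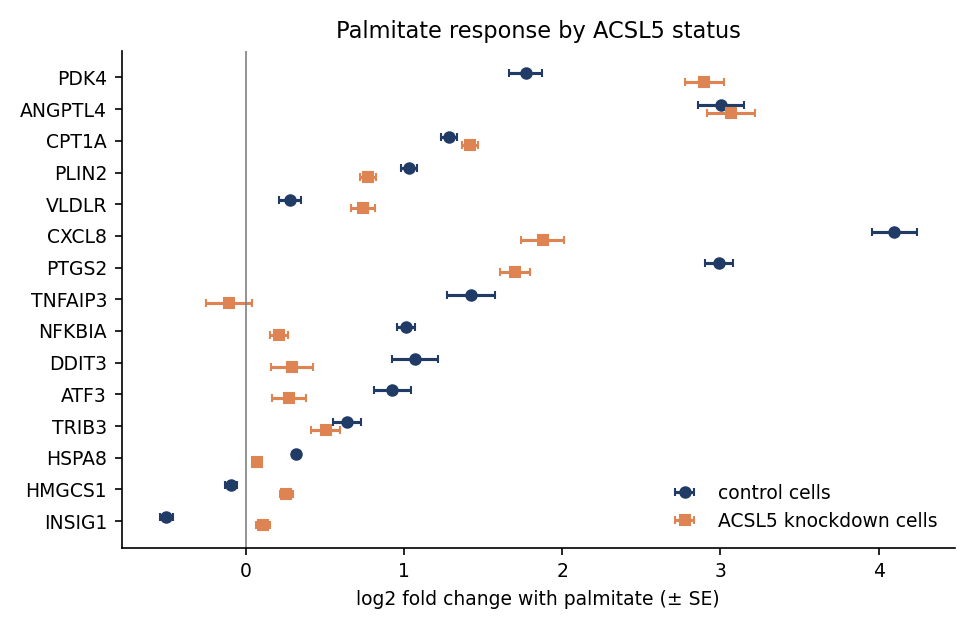
Log2 change with palmitate ± SE of 15 genes in control and in knockdown cells (n = 3 libraries per group). CXCL8 stands at 4.10 in control and 1.88 in knockdown cells, and CPT1A at 1.29 and 1.42.

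The knockdown was also compared under palmitate, where the NF-kB targets CXCL8 and PTGS2 were lower in knockdown cells. STXBP6 rose by 5.87 (SE 0.27, 10 counts in shControl_PA, interval 5.03 to 6.99), SUSD2 by 2.99 (SE 0.11), the matrix protein gene MATN2 by 2.70 (SE 0.15), ANKRD1 by 2.68 (SE 0.05), the lipid flippase ATP8B1 by 2.47 (SE 0.14) and SPHK1 by 2.46 (SE 0.11). JCAD fell by 2.09 (SE 0.12), the polarity gene MPP7 by 2.05 (SE 0.16), AGR2 by 2.03 (SE 0.12) and the receptor kinase GRK3 by 2.01 (SE 0.17), JCAD and GRK3, like the rising STXBP6, carrying the heptamer ACTACTT in the 3′ UTR. DNAJC25-GNG10 was called at -3.03 (SE 0.79), a read-through gene with 93.4% of its 50-base sequences found elsewhere. PTGS2 fell by 1.47 (SE 0.08) and CXCL8 fell by 1.32 (SE 0.11), the latter to 11.7 ± 1.39 CPM in shACSL5_PA against 29.2 ± 1.12 CPM in shControl_PA.

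There were 7432 genes called, 3591 higher and 3841 lower (48.3% higher, 47.9% to 51.8% over the alternatives), and 713 changed at least 2-fold. NF-kB targets fell in 12 of 23 members and rose in 5 (13 and 5 adjusted over the list alone, adjusted p = 0.0107, adjusted p = 0.112 with an estimated correlation). ER chaperones fell in 15 of 24 and rose in 0, also adjusted over the list alone (adjusted p = 0.000878, adjusted p = 0.0988 with an estimated correlation). SEL1L stood at -0.69 (SE 0.05, heptamer in its 3′ UTR) and HSPA5 at -0.35 (SE 0.02). Integrated stress response genes fell in 21 of 35 and rose in 7 (21 and 8 adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.160 with an estimated correlation), ASNS by 0.90 (SE 0.04). NRF2 targets fell in 13 of 22 and rose in 5, also adjusted over the list alone (adjusted p = 0.0126, adjusted p = 0.112 with an estimated correlation). GCLM stood at -0.71 (SE 0.05) and NQO1 at -0.58 (SE 0.03). Hypoxia genes fell in 16 of 27 and rose in 5 (17 and 5 adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.153 with an estimated correlation). NDRG1 stood at -0.84 (SE 0.04) and P4HA1 at -0.83 (SE 0.04). Interferon-stimulated genes fell in 15 of 27 and rose in 2, also adjusted over the list alone (adjusted p = 0.00213, adjusted p = 0.112 with an estimated correlation). Immediate early genes fell in 13 of 25 and rose in 4, also adjusted over the list alone (adjusted p = 0.00213, adjusted p = 0.0988 with an estimated correlation). PHLDA1 stood at -0.75 (SE 0.02) and DUSP6 at -0.53 (SE 0.03).

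Mesenchymal genes fell in 14 of 23 and rose in 5, also adjusted over the list alone (adjusted p = 0.00213, adjusted p = 0.0988 with an estimated correlation). CDH11 stood at -1.09 (SE 0.05). Epithelial genes fell in 7 of 13 and rose in 1, also adjusted over the list alone (adjusted p = 0.0126, adjusted p = 0.0988 with an estimated correlation), CLDN4 by 1.42 (SE 0.08). Luminal genes fell in 5 of 9 and rose in 0, also adjusted over the list alone (adjusted p = 0.0126, adjusted p = 0.167 with an estimated correlation). The lung metastasis signature, a list of genes tied to lung spread of MDA-MB-231 cells, fell in 7 of 15 and rose in 3 (8 and 3 adjusted over the list alone, adjusted p = 0.0489, adjusted p = 0.112 with an estimated correlation). MAN1A1 stood at -0.94 (SE 0.06), TNC at -0.81 (SE 0.04) and FSCN1, an actin bundler, at 0.73 (SE 0.05). The call was lost without shACSL5_PA replicate 1 (adjusted p = 0.0589). The signature was not called with the knockdown without palmitate (adjusted p = 0.602) or in the interaction. Nor was it called with palmitate in control cells (adjusted p = 0.136) or in knockdown cells (adjusted p = 0.201). S phase genes rose in 16 of 27 and fell in 2, also adjusted over the list alone (adjusted p = 0.000726, adjusted p = 0.0988 with an estimated correlation), with histone transcripts at 98.3 ± 6.27 CPM in shACSL5_PA. OXPHOS subunits rose in 17 of 36 and fell in 3 (18 and 4 adjusted over the list alone, adjusted p = 0.00533, adjusted p = 0.192 with an estimated correlation). Heat shock genes rose in 10 of 16 and fell in 3 (11 and 3 adjusted over the list alone, adjusted p = 0.00213, adjusted p = 0.0988 with an estimated correlation). YAP targets rose in 12 of 23 and fell in 4, also adjusted over the list alone (adjusted p = 0.0126, adjusted p = 0.105 with an estimated correlation).

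**Figure D3:**
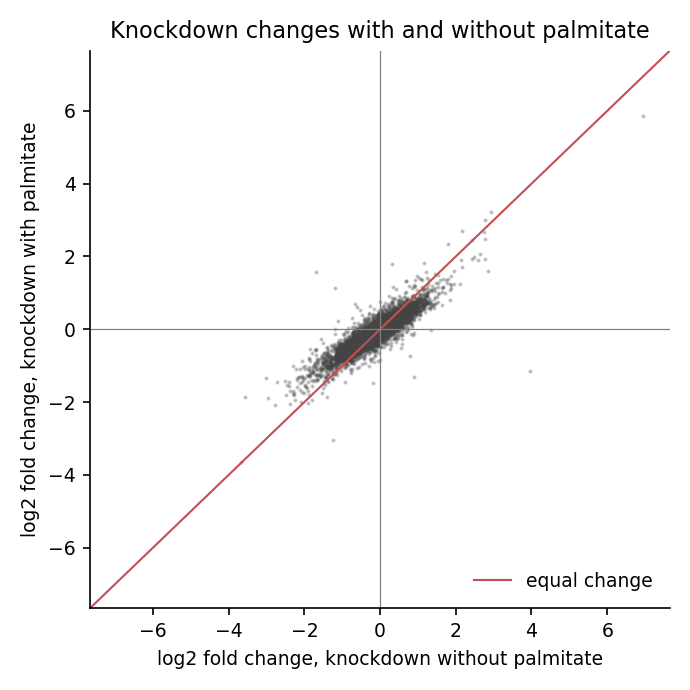
Log2 change with the knockdown without palmitate (horizontal) and with palmitate (vertical) for 10938 genes with a mean of at least 5 CPM, each point a gene. The correlation across genes is 0.899 and the spread with palmitate is 0.730 times that without.

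The interaction asks whether the response to palmitate differed between control and knockdown cells. CXCL8 responded less in knockdown cells, with an interaction of -2.22 (SE 0.21, log2), as did TNFAIP3 (-1.53, SE 0.21), DUSP1 (-1.38, SE 0.06), PTGS2 (-1.29, SE 0.14) and EGR1 (-1.01, SE 0.07). DUSP1 stood at 36.7 ± 2.01 CPM in shControl and 107 ± 1.74 CPM in shControl_PA, against 93.7 ± 2.05 and 105 ± 2.49 CPM in the knockdown groups. ADM, at 22.8 ± 1.51 CPM in shACSL5, had an interaction of -1.25 (SE 0.18). In the other direction, DPYSL3 had an interaction of 1.70 (SE 0.18), AFAP1L2 of 1.68 (SE 0.33), the actin bundler LCP1 of 1.35 (SE 0.15), SETBP1 of 1.35 (SE 0.26), the desmosome gene DSP of 1.29 (SE 0.09) and PDK4 of 1.13 (SE 0.17).

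There were 2139 genes called, 1052 with a positive and 1087 with a negative interaction (49.2% positive, from 42.5% with DESeq2 to 59.9% with library sizes alone). For 1017 of them the palmitate change was called in control cells alone, for 611 in knockdown cells alone, for 226 in both with opposite signs, for 166 in both with one sign and for 119 in neither. The S phase list had 13 of 27 genes with a negative and 0 with a positive interaction (15 and 0 adjusted over the list alone, adjusted p = 9.69e-08). MCM5 stood at -0.30 (SE 0.05) and FEN1 at -0.29 (SE 0.05). NRF2 targets were negative in 8 of 22 and positive in 2 (9 and 2 adjusted over the list alone, adjusted p = 3.63e-05). FTL stood at -0.74 (SE 0.04), FTH1 at -0.45 (SE 0.04) and TXNRD1 at -0.47 (SE 0.04). Heat shock genes were negative in 6 of 16 and positive in 0 (9 and 0 adjusted over the list alone, adjusted p = 7.4e-05). HSPA8 and HSPD1 both stood at -0.24. Cholesterol synthesis genes were positive in 8 of 23 and negative in 0 (9 and 0 adjusted over the list alone, adjusted p = 3.63e-05). INSIG1 stood at 0.61 (SE 0.06) and MSMO1 at 0.56 (SE 0.06). Mesenchymal genes were positive in 11 of 23 and negative in 1 (14 and 2 adjusted over the list alone, adjusted p = 8.95e-05). TNC stood at 0.63 (SE 0.06) and TGFBI at 0.58 (SE 0.08).

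These 5 interaction lists were also called with an estimated correlation, at adjusted p = 0.0263, 0.0263, 0.0198, 0.0198 and 0.0447 in the order given. In the other comparisons with palmitate as the treatment, every list call given without such a p held as well. Of 24 ER chaperones 7 were negative and 0 positive (8 and 0 adjusted over the list alone, adjusted p = 0.000536, adjusted p = 0.103 with an estimated correlation). HSPA5 stood at -0.27 (SE 0.03) and CANX at -0.31 (SE 0.03). SREBP1 targets were positive in 4 of 15 and negative in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.00484, adjusted p = 0.319 with an estimated correlation). ACSS2 stood at 0.57 (SE 0.11) and SCD at 0.32 (SE 0.03). Integrated stress response genes were negative in 8 of 35 and positive in 3 (11 and 5 adjusted over the list alone, adjusted p = 0.0389, adjusted p = 0.345 with an estimated correlation). SLC3A2 stood at -0.39 (SE 0.05). Without shControl replicate 1, shACSL5 replicate 3 or shControl_PA replicate 1 this call was lost (0.0790, 0.0780 and 0.0572). NF-kB targets were negative in 4 of 23 and positive in 2 (5 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.0740, adjusted p = 0.319 with an estimated correlation). PPAR targets (3 of 14 positive and 1 negative, 4 and 1 adjusted over the list alone) and epithelial genes (3 of 13 positive and 1 negative, 5 and 1 adjusted over the list alone) were not called either. Both had adjusted p = 0.0513, and 0.319 and 0.144 with an estimated correlation. PLIN2 had an interaction of -0.26 (SE 0.07, adjusted p = 0.0152, and 0.0541 without shControl replicate 1). ANGPTL4 stood at 0.06 (SE 0.23, adjusted p = 0.901), CPT1A at 0.13 (SE 0.07, adjusted p = 0.246), TRIB3 at -0.13 (SE 0.13, adjusted p = 0.549) and IL6 at 0.89 (SE 0.66, adjusted p = 0.414). No list call of either knockdown comparison held with an estimated correlation, against 12 of 16 in palmitate-treated control cells, 11 of 14 in palmitate-treated knockdown cells and 5 of 8 in the interaction.

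**Figure D4:**
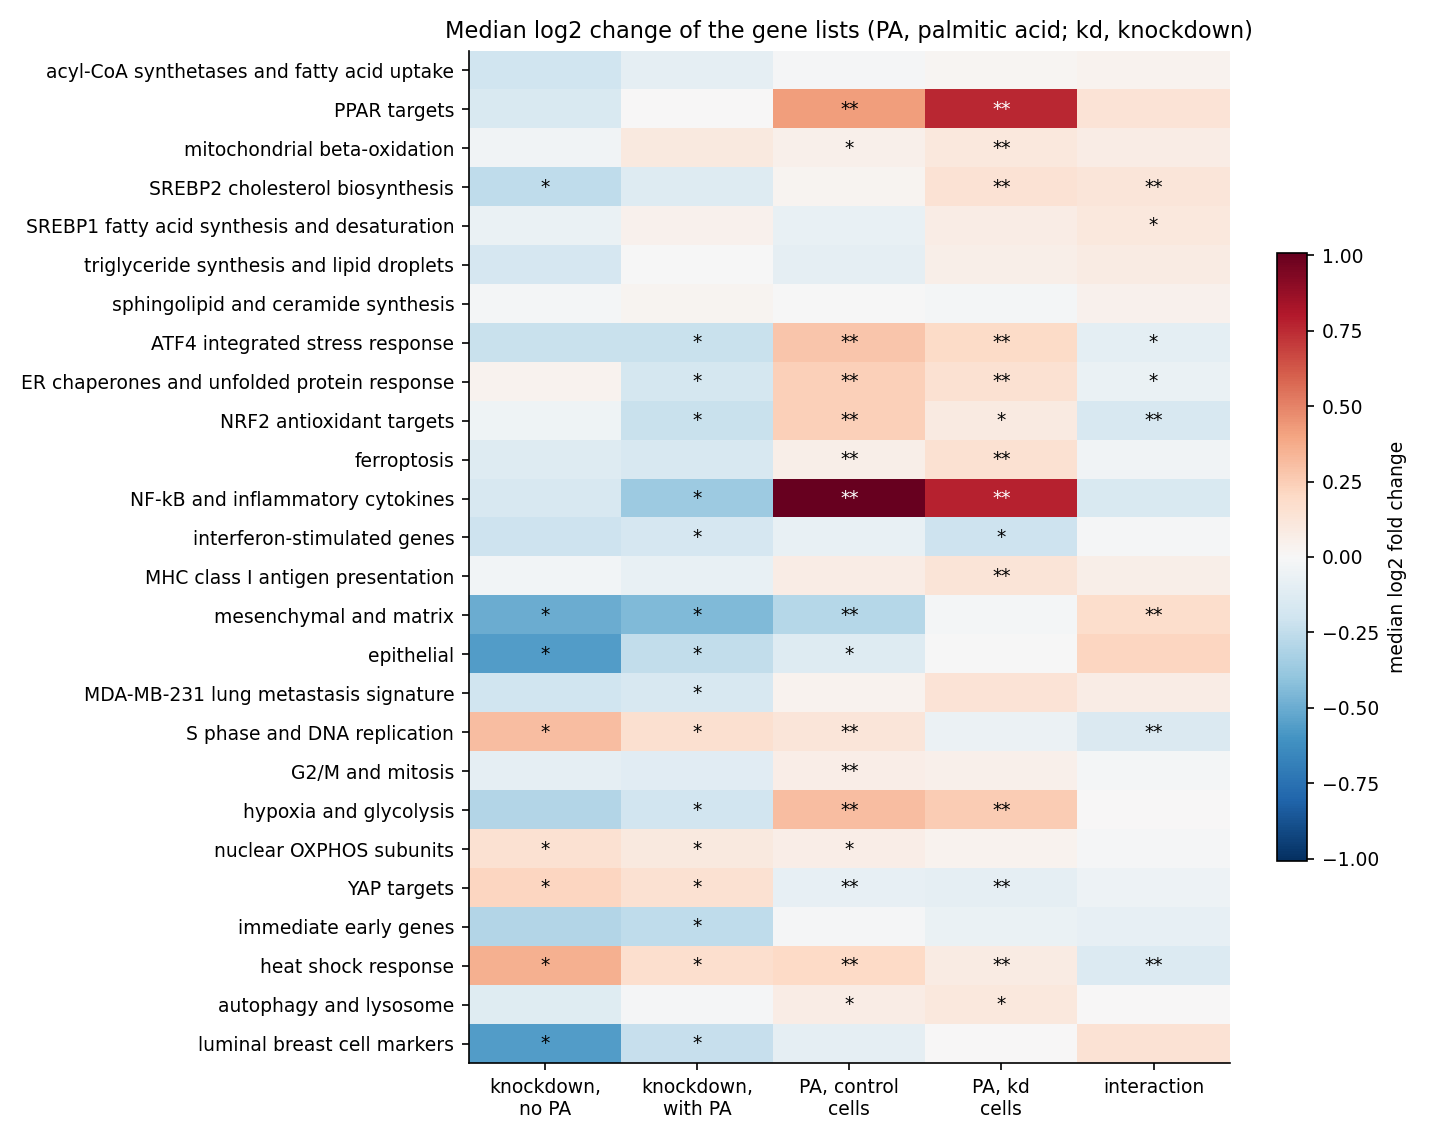
Median log2 change of each tested gene list (vertical) in the 5 comparisons (horizontal), with 1 star for a list called at an adjusted p under 0.05 with the preset correlation and 2 stars where the call also held with an estimated correlation. NF-kB genes have a median of 1.01 with palmitate in control cells and 0.77 in knockdown cells.

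Both knockdown comparisons called 3100 genes higher and 3340 lower, against 1065 and 1254 for independent lists, and 34 and 18 genes had opposite signs. Fold changes correlated at r = 0.899 across 10938 genes, which are not independent replicates. The spread of the changes, with noise subtracted, was smaller with palmitate by a ratio of 0.730 (0.717 to 0.742 over left-out libraries). The palmitate comparisons shared 657 higher and 649 lower genes, against 269 and 195 for independent lists (one-sided Fisher's exact p = 5.36e-133 and 3.63e-217). This test takes genes as independent, which they are not. Another 111 and 115 genes had opposite signs, against 218 and 241 for independent lists. The changes had r = 0.433 and a ratio of spreads of 0.873 in knockdown against control cells (0.813 to 0.896 over left-out libraries). Leaving out each library in turn gave this ratio a standard error of 0.067, so the spreads are not clearly unequal. The main effects of knockdown and palmitate, averaged over the other factor, had r = 0.013 across genes. This lay within the range of -0.051 to 0.043 of 20 simulations with no effect. The simulations hold noise alone, so the range does not show that the effects are unrelated.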

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

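The tests of the weaker palmitate response and of the smaller knockdown changes were chosen only after those results were seen, while the splits of the libraries were planned. The interaction drew attention because it tests a difference between the responses of control and knockdown cells, and 2139 genes passed it. In 100 random splits of the 12 libraries into 4 groups of 3, the real one included, 1 gave as many genes and the highest other gave 330. These splits spread the knockdown and palmitate effects over the groups, and their median dispersion was 0.0476 against 0.00203 in the real one, so they are no fair null for the interaction. In a test added later, the additive effects of knockdown and palmitate were moved to the assigned groups in the same 100 splits (median dispersion 0.00294). Of these, 1 gave as many genes, the real one, and the highest other gave 907. This argues against a chance split of these 12 libraries. It cannot exclude chance differences between cultures, since the replicates of a group may not be separate cultures. Lists whose response differed were SREBP2 targets (adjusted p = 3.63e-05), SREBP1 targets (0.00484), the integrated stress response (0.0389), ER chaperones (0.000536), NRF2 targets (3.63e-05), mesenchymal genes (8.95e-05), S phase genes (9.69e-08) and heat shock genes (7.4e-05). With an estimated correlation 3 of these calls were lost, SREBP1 targets (0.319), the integrated stress response (0.345) and ER chaperones (0.103). The integrated stress response was also lost without shControl replicate 1 (0.0790), shACSL5 replicate 3 (0.0780) or shControl_PA replicate 1 (0.0572). Without palmitate, S phase genes were mostly higher in knockdown cells and SREBP2 and mesenchymal genes mostly lower, opposite to their interactions. Starting levels, and the libraries that both contrasts share, may thus be part of these differences. Their part was not tested for these lists. For the pairwise comparisons only 10 splits exist, too few for a share under 0.05. The real splits called 9164 (knockdown), 4217 (palmitate in control cells), 3216 (palmitate in knockdown cells) and 7432 genes (knockdown with palmitate), the highest other splits 1, 0, 0 and 0, and in each case only 1 split, the real one, called as many.

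Among single genes, the response to palmitate was more positive in knockdown cells for RN7SL2 (interaction 3.27, log2), RN7SL1 (2.34), DPYSL3 (1.70), AFAP1L2 (1.68), LCP1 (1.35), SETBP1 (1.35), PDK4 (1.13) and SCD (0.32). It was more negative for RIOX1 (-5.11), CXCL8 (-2.22), TNFAIP3 (-1.53), DUSP1 (-1.38), PTGS2 (-1.29), ADM (-1.25), DDIT3 (-0.78), ATF3 (-0.66) and PLIN2 (-0.26, adjusted p = 0.0541 without shControl replicate 1, and 0.00852 to 0.0541 over its alternatives). RN7SL2 was at 28.4 CPM in shControl replicate 1 against 2.57 and 8.62 CPM in replicates 2 and 3. Without that library the interactions of RN7SL2 and RN7SL1 were 2.06 and 1.39. RIOX1 was past the threshold with edgeR but not with DESeq2 (adjusted p = 0.104, the highest over its alternatives, the lowest being 1.43e-62 with no low-count filter). Its interaction shares the scattered control libraries described for its knockdown change, so the size of -5.11 is uncertain.

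The first pattern weighed is the smaller rise with palmitate in knockdown cells of heat shock genes and of 4 of 23 NF-kB genes (CXCL8, TNFAIP3, PTGS2 and NFKBIA), while the NF-kB list was not called (adjusted p = 0.0740). Less palmitate reaching those cells would lower the response of PPAR targets too. The 9 PPAR targets that rose in control cells had a median interaction of 0.131 (0.0996 to 0.236 over left-out libraries), with 2 of them below 0. Of the 9, 3 had a called positive interaction, among them PDK4 and VLDLR, and 1 a called negative one, PLIN2. Without palmitate PDK4 and VLDLR were lower in knockdown cells (log2 -1.52 and -1.26) and PLIN2 was higher (0.42). Starting levels may thus be part of these differences too, and the test does not settle how much palmitate reached the cells. Within these libraries, a start already raised to the same end level is argued against for the 4 NF-kB genes. The same 4 genes were chosen by their interaction without a pair of treated libraries. They were lower in the knockdown library of that pair in each of 3 pairs (log2 -1.56 to -0.519, median -1.04). The pairs share only a replicate number, which does not pair the samples. The treated libraries used for the choice may be technical repeats of those left out, so these values are no independent replication. Without palmitate CXCL8 (0.91), TNFAIP3 (0.80) and NFKBIA (0.27) were higher in knockdown cells and PTGS2 stood at -0.18 (adjusted p = 0.167), so a raised start may be part of the difference for the first 3. The 14 NF-kB genes that rose in control cells had a median knockdown difference of 0.0511 without palmitate and -0.633 with it (-0.686 to -0.522 over left-out libraries), a value that shares libraries with the choice of genes. Over the whole list the medians were -0.161 (7 higher, 6 lower) and -0.366 (5 higher, 12 lower, adjusted p = 0.112 with an estimated correlation), so the list as a whole decides nothing. For the 12 heat shock genes that rose in control cells, the median knockdown difference was 0.360 without palmitate (0.343 to 0.368) and 0.172 with it. A start already raised by the knockdown would give such values. The difference without palmitate shares its libraries with the interaction, however, so genes with a negative interaction tend to show a raised start, and this is weak evidence. The medians over all 16 measured members were the same 0.360 and 0.172, although the list was called in neither comparison with an estimated correlation (adjusted p = 0.0717 and 0.0988). A weaker response of these genes to palmitate through the loss of ACSL5 stays open, untested, as do changes made by the hairpin apart from ACSL5.

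The second pattern is that knockdown changes were smaller under palmitate. The ratio of spreads was 0.730 after noise between libraries was subtracted (0.717 to 0.742 over left-out libraries). That noise had an SD of 0.0869 without and 0.0868 with palmitate, small beside spreads of 0.526 and 0.384. This argues against noise between these libraries as the cause. The noise estimate was shared by all groups, and noise between cultures was not tested. A weaker knockdown is argued against by ACSL5 itself, whose interaction was 0.029 (SE 0.10), and scaled by the ratio its change would have been -2.68, and it was -3.65. The ratio was 0.730 with RLE factors and with library sizes alone too, but a size factor shifts all genes of a comparison alike and cannot move it, so this says nothing about the choice of normalization. An effect of palmitate on the consequences of the knockdown stays open, untested. Of the 2139 interaction genes 2049 had a sign opposite to the knockdown change without palmitate, part of which comes from the libraries both share.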

How the results depend on the processing

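The alternative without genes holding the heptamer and the ratio of spreads with library sizes alone were chosen only after the data were seen. The number of called genes stayed within 1.5 times its value under both other scalings, both filters, DESeq2, the fit to compared groups only (not run for the interaction, which needs all groups) and the heptamer alternative. A 2-fold threshold, stricter by construction, gave 1485 genes (knockdown), 240 (palmitate in control cells), 136 (palmitate in knockdown cells), 713 (knockdown with palmitate) and 111 (interaction). DESeq2 called 8632, 3803, 2833, 6857 and 1915 in that order, and without the 1301 genes holding the heptamer the counts were 8185, 3805, 2744, 6557 and 1886. The counts without those genes come from the same fit with p adjusted again, so they could change little. Over left-out libraries the counts ran from 8569 to 9243, 3418 to 4324, 2402 to 3226, 6758 to 7483 and 1657 to 2138. With a replicate block the counts were 9197, 4302, 3363, 7489 and 2261. The block changed no named gene and 1 list, G2/M with the knockdown under palmitate (adjusted p = 0.0336 against 0.0552). Over all alternatives this list ran from 7.51e-05 with fry to 0.166 with an estimated correlation. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.042 to 0.080, and 0 of 18 correlations were over 0.1. With an estimated correlation 0 lists were called for the knockdown, 0 for the knockdown with palmitate and 5 for the interaction, while fry, which does not compare a list with other genes, called 22 for the knockdown, 22 for palmitate in knockdown cells and 15 for the interaction. Fry turned the direction of 2 uncalled lists with the knockdown, NRF2 targets (adjusted p = 0.00537, up to 0.999 over the alternatives) and ferroptosis (0.0143, up to 0.936); the cause was not tested. The correlation across genes ran from 0.879 (without shControl replicate 2) to 0.898 for the knockdown changes and from 0.377 (without shControl replicate 2) to 0.441 for the palmitate changes; the cause was not tested. Of 533 results for named genes 18 changed their side of the threshold under some left-out library and 0 reversed; 4 had no adjusted p with DESeq2. ACSL4 with the knockdown under palmitate was lost without shControl_PA replicate 2 (adjusted p = 0.0641, the highest of 0.000321 to 0.0641). Of 130 list results 2 calls were lost without some library, the integrated stress response in the interaction and the lung metastasis signature with the knockdown under palmitate, as given with those results. Another 12 were gained, and 0 reversed. Those gained were G2/M with the knockdown under palmitate (without 7 of the libraries in turn, adjusted p = 0.0349 to 0.0493) and the interactions of PPAR targets, epithelial genes, NF-kB genes and beta-oxidation. The PPAR interaction was gained without 5 libraries in turn (0.0178 to 0.0413). Over all alternatives it ran from 0.0103 with fry to 0.319 with an estimated correlation. The epithelial interaction was gained without 5 libraries in turn (0.0241 to 0.0477) and with RLE factors (0.0486). Over all alternatives it ran from 0.000288 with fry to 0.144 with an estimated correlation. The NF-kB interaction was gained without shControl_PA replicate 2 or shACSL5_PA replicate 1 (0.0456 and 0.0413). Over all alternatives it ran from 0.00388 with fry to 0.319 with an estimated correlation. The rest were beta-oxidation with the knockdown under palmitate, hypoxia with the knockdown, MHC class I and interferon-stimulated genes with palmitate in control cells, and S phase, immediate early and OXPHOS genes with palmitate in knockdown cells. Without the genes holding the heptamer 1 list call was lost, NRF2 targets with the knockdown under palmitate (0.0515, in a range of 8.39e-07 with fry to 0.112 with an estimated correlation). Another 5 were gained: G2/M with the knockdown under palmitate (0.0259), the interactions of PPAR targets (0.0381), epithelial (0.0381) and immediate early genes (0.0198, in a range of 0.00116 with fry to 0.319 with an estimated correlation), and SREBP1 targets with palmitate in control cells (0.0105, the lowest, up to 0.410). The cause of these changes was not tested. At these library sizes and 3 libraries per group the simulation recovered 24% of the smallest simulated interactions (smaller than 1.5-fold), 50% of 1.5-fold and 74% of 2-fold ones, so small differences between responses are the least certain. The simulation changed far fewer genes than were called here, so these shares need not hold for the real data.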

Other observations

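The test of heptamers was planned, and the shares of genes holding the leading heptamer and the fit without them were chosen only after its result was seen. Lipid genes outside the lists called above moved in both directions with the knockdown. Of 16 acyl-CoA synthetase and fatty acid uptake genes 8 fell and 2 rose (8 and 3 adjusted over the list alone, list adjusted p = 0.438), the fatty acid transporter SLC27A1 by -0.98 (SE 0.08). Of 23 triglyceride and lipid droplet genes 11 fell and 8 rose, also adjusted over the list alone (adjusted p = 0.680). GPAT3, which adds the first acyl chain to glycerol 3-phosphate, fell by 1.15 (SE 0.06), and the phosphatidate phosphatases LPIN1 and LPIN2 fell by 0.62 (SE 0.05) and 0.70 (SE 0.03). Of 23 sphingolipid genes 8 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.846). The sphingosine kinases SPHK1 and SPHK2 rose by 2.43 (SE 0.11) and 1.05 (SE 0.10), while the ceramidase ASAH1 fell by 0.75 (SE 0.05) and the sphingomyelin synthase SGMS1 by 0.50 (SE 0.05). None of these lists was called in any of the 5 comparisons with the preset correlation.

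Several genes had opposite responses to palmitate in the 2 cell types, each with a called interaction. The interferon-induced gene IFIT2 rose by 0.22 (SE 0.06) in control cells, a call lost without shControl replicate 3 (adjusted p = 0.0625, the highest of 8.53e-05 to 0.0625), and fell by 0.53 (SE 0.06) in knockdown cells. TNC fell by 0.29 (SE 0.04) in control cells and rose by 0.34 (SE 0.05) in knockdown cells. Of markers of other cells, 1 immune gene was measured, the lysosomal CD68, which rose by 0.45 (SE 0.07) with the knockdown. Of 3 lung epithelial markers NKX2-1 fell by 0.25 (SE 0.06), and AGER (-0.41, SE 0.37) and NAPSA (1.03, SE 0.55) were not called. Of 13 mitochondrially encoded genes 0 were measured.

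A hypothesis fixed before the data were examined was that the hairpin silences other transcripts through a short seed match in their 3′ UTR. Of 16174 heptamers tested over 10326 genes, ACTACTT, found in all 5 coding transcripts of ACSL5, went with the strongest fall (t = -7.15 without and -8.61 with palmitate, 1.73 for palmitate in control cells), past the Bonferroni bound of 4.67, and the next unrelated heptamer, AGGGCGA, had t = -4.23. The 1168 genes holding it had a median log2 change of -0.24 against 0.01 for the rest, and the share holding it was 27.6% of genes that fell at least 2-fold, 9.62% of uncalled genes and 6.34% of genes that rose, without correction for UTR length. Off-target silencing by a hairpin with this seed would give such values, but 19.8% of all heptamers occur in ACSL5. For falls 7 heptamers passed the bound, 3 of them in ACSL5 transcripts. The 7 overlap in sequence and are not separate findings. For rises 14 heptamers passed, led by GTCGCCC (t = 8.89, and 6.01 for palmitate in control cells), so such an association is not specific to a hairpin. The hairpin sequence is not given in the sources used here, so which of the falling genes respond to ACSL5 itself stays open. Without the genes holding the heptamer 8185 were called with the knockdown. That count keeps the same fit, drops 1301 genes and adjusts p again. It therefore cannot tell off-target effects from those of ACSL5.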
